A study of Mus musculus with 21 samples.

How the data were processed

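The series holds small RNA sequencing of whole kidney from male BALB/c mice, aged 12 weeks, that received folic acid at 250 mg/kg. Folic acid at such a dose injures the renal tubules and is a standard model of acute kidney injury that goes on to fibrosis. The course runs from day 0 to day 28 in 7 groups, with 3 libraries per day and 21 libraries in all. Per the labels' protocols, the libraries were made with a TruSeq small RNA kit and read on an Illumina HiSeq instrument. The labels do not state that the 3 libraries of a day came from separate animals, so p-values measure the spread between these libraries.

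The authors deposited 1 table of CPM (reads scaled to a common library total) for 1125 mature miRNAs. The file calls its values counts, but each column sums to the same round total, so the deposited values are CPM of the reads assigned to miRNAs. Per the submitters' processing notes, CASAVA 1.8 and the mouse genome build mm9 were used. The aligner, the counting tool and the miRBase release are not given in the sources used here. Reads assigned to miRNAs were counted whole, and each column is a set of multiples of the CPM that 1 read is worth. Whole reads were recovered from these steps for 100% of the values, within a tolerance of 0.05 of a read, and the largest distance from a whole read was 0.035. The recovered totals ran from 2875675 to 7110546 reads per library, with a median of 4494595. These totals cover reads assigned to miRNAs. A count of 0 allows up to 3 reads, which is 1.04 CPM in the shallowest library and 0.422 CPM in the deepest, and this limit covers counting error only.

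Of the 1125 miRNAs, 250 had no read in any library. The edgeR function filterByExpr, run on the recovered reads with its minimum count of 10, left 431 miRNAs. Differential abundance was tested with limma (limma-trend) on log2(CPM + 1), after TMM scaling of the CPM, in 1 fit over all 21 libraries with a mean for each day. A miRNA was called when its Benjamini-Hochberg adjusted p was under 0.05. Adjusted p-values in the text come from this limma fit unless another tool is named. Fold changes are on the log2(CPM + 1) scale, which understates the change of scarce miRNAs. Levels are given as TMM-scaled CPM, mean ± SD of 3 libraries. The comparisons were each later day against day 0, an F test over all days, the mean of days 7, 14 and 28 against the mean of days 1, 2 and 3 (late against early), and each day against the one before. The design set in advance assumed counts and the edgeR quasi-likelihood test. Because the unit was CPM, that test on the recovered reads became an added alternative. It called 105, 193, 211, 225, 184 and 52 miRNAs on days 1, 2, 3, 7, 14 and 28 against day 0, and 159 in late against early.

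The same design fixed 21 lists of miRNAs and the rule for the miRNAs named in the text. The rule took, for each day against day 0 and for late against early, the 6 largest rises and the 6 largest falls among called miRNAs with a mean of at least 10 CPM over the 21 libraries and no overlap of the libraries compared. Late against early needed no such separation. The rule also took members of the fixed lists and the 10 most abundant miRNAs at day 0. The lists were kidney-enriched miRNAs, the miR-30, miR-200, miR-29, let-7 and miR-15/16 families, miRNAs associated with injury and fibrosis, miRNAs induced by NF-kB or by p53, hypoxia miRNAs, the miR-17 to miR-92 clusters, the miR-183 and the miR-322/miR-503 clusters, the imprinted Dlk1-Dio3 cluster, and markers of other cells or organs (mesenchymal, smooth muscle, leukocyte, endothelial, erythroid, striated muscle, and other organs). The injury and fibrosis list was drawn up from general knowledge of this model. Work on folic acid kidneys, perhaps including these samples, went into that knowledge, so the list is not independent evidence of its direction. All mesenchymal miRNAs are also in it, as are miR-146b-5p, miR-21-5p, miR-132-3p and miR-212-3p of the NF-kB list. So are miR-18a-5p of the miR-17 to miR-92 list, miR-34a-5p of the p53 list and miR-192-5p of the kidney-enriched list. The results of these lists are therefore not separate from it. Lists with 3 or more tested members, 18 in all, were compared with the other miRNAs by limma's camera with a preset correlation of 0.01 between members, in 126 tests over 7 comparisons. Camera was run on the log2(CPM + 1) values, while the design named log2 CPM with a prior count of 2, which was run as an added alternative. Camera passed 36 of them. With the correlation estimated from the data it passed 0, with 26 at an unadjusted p under 0.05. The rotation test fry, which asks whether a list's members move one way on balance and does not compare them with other miRNAs, passed 73.

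Several rows cannot be separated. miR-199a-3p and miR-199b-3p held identical reads in all libraries, as did 4 rows of miR-466 and 3 further pairs, 12 tested rows in all. miR-199a-3p and miR-199b-3p are both in the mesenchymal list and in the injury and fibrosis list. The counts of these lists therefore hold the same reads more than once. miR-486-5p and miR-3107-5p differed by a fraction of 0.0017 in their summed reads. Host genes and neighbours within 10 kb came from GENCODE M21 and the RefSeq gene table of assembly GRCm38.p6, where 372 of the 431 tested miRNAs matched 1 gene. That assembly differs from mm9, so it was used for names and neighbours and gives no coordinates here. Of the members of fixed lists, miR-194-5p, miR-30c-2-3p and miR-29b-1-5p had no row under those names, and rows named miR-194-2-5p, miR-30c-3p and miR-29b-5p were not put in their place. miR-1a-3p had a row but did not pass the filter.

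Alternatives chosen before the data were examined were RLE, upper-quartile and library-total scaling, no filter on low values, a filter of 10 CPM in 3 libraries, DESeq2 on the recovered reads, robust empirical Bayes, a replicate block, a fit of the 2 days compared, and leaving out each library in turn. Chosen after seeing the data were the edgeR test, pseudocounts of 0.25 and 5 CPM, leaving out rows with identical reads, the prior count of 2, and the fit of the 2 days for single miRNAs. The limma test was tested on simulated data, with counts drawn from the real means and library sizes for day 3 against day 0, over 431 miRNAs. It recovered 52.2% of those changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold, and called 3 of 231 unchanged miRNAs. With nothing changed, in day 7 against day 0, it called 0 of 431. Camera found 10 of 10 simulated lists that changed 2-fold at day 3 and 0 of 40 unchanged lists. The simulated members were drawn independently of each other. In the real lists the estimated correlation ran from 0.018 (smooth muscle) to 0.92 (erythroid). The simulation therefore cannot tell how camera does on lists whose members move together. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0. Libraries of a day correlated at r between 0.988 and 0.997 over miRNAs, which are not independent of each other. No 2 libraries of a day agreed within sampling noise, as chi-square per degree of freedom ran from 23.6 to 277.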

Results

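Mature miRNAs were measured in whole kidney over 28 days after folic acid, with day 0 as the reference, 3 libraries per day and 7 days in all. The labels do not say whether the day 0 mice had received an injection. No later day has a group without folic acid among the samples. Comparisons with day 0 therefore do not separate folic acid from injection, vehicle, age or day of collection. Library depth ran from 2875675 to 7110546 reads assigned to miRNAs, and between 587 and 683 miRNAs had a read in a library. At day 0 the 10 most abundant miRNAs held 73.8% ± 0.98 of the reads (SD, n = 3). The most abundant were miR-10a-5p with 12.6% ± 1.59, miR-10b-5p with 11.8% ± 1.07, miR-22-3p with 11.5% ± 0.829 and miR-192-5p, a kidney-enriched miRNA, with 11.4% ± 0.887. Next came miR-30a-5p with 7.60% ± 0.370 and miR-143-3p, known from smooth muscle, with 6.88% ± 0.985. miR-26a-5p, miR-27b-3p, miR-378-3p and miR-30e-5p held between 2.59% and 3.62%.

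The course as a whole was tested first. Of 431 miRNAs, 272 (63.1%) changed on at least some day (F test of limma, adjusted p under 0.05). Against day 0, 109 miRNAs were called on day 1, 187 on day 2, 213 on day 3, 226 on day 7, 185 on day 14 and 56 on day 28. The first principal component held 41.1% of the variance. Its mean moved from -10.46 at day 0 to 6.77 at day 7 and back to -3.92 at day 28. Day 14 had the widest spread on it (SD 3.14, n = 3). miR-21-5p, miR-132-3p, miR-146b-5p, miR-142-3p, miR-223-3p, miR-31-5p and let-7i-5p were among 19 miRNAs higher than day 0 on all 6 later days. miR-101a-5p, miR-101a-3p, miR-101c, miR-187-5p, miR-193-3p and miR-33-5p, which lies in an intron of the sterol regulator Srebf2 in GRCm38, were the 6 lower on all of them. All comparisons with day 0 share the same 3 reference libraries, which may add to such overlap.

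**Figure D1:**
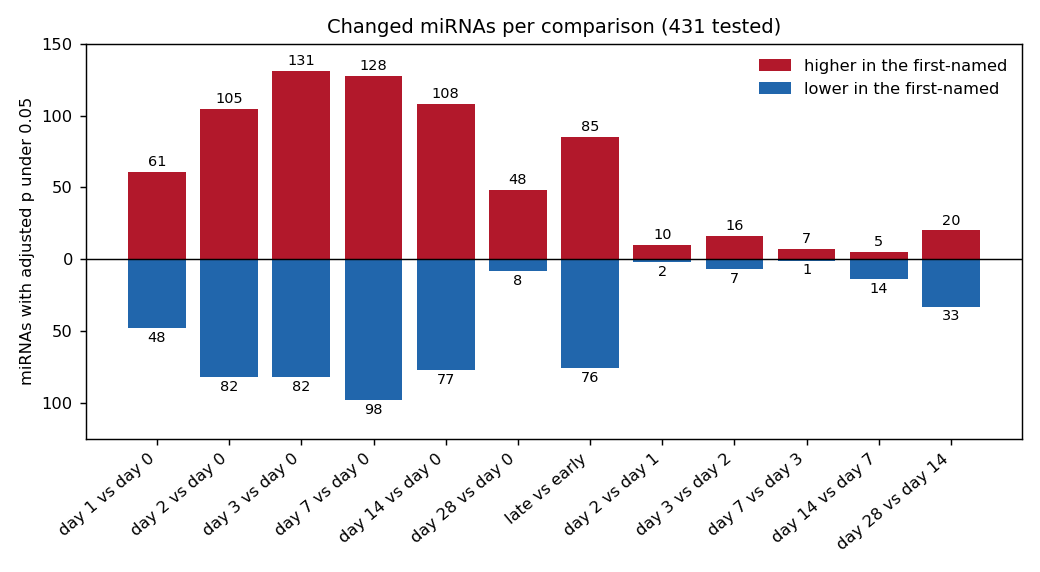
Number of miRNAs with adjusted p under 0.05 in each comparison, out of 431 tested, with those higher in the first-named group above 0 and those lower below 0. The count was 226 for day 7 against day 0 and 56 for day 28.

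**Figure D2:**
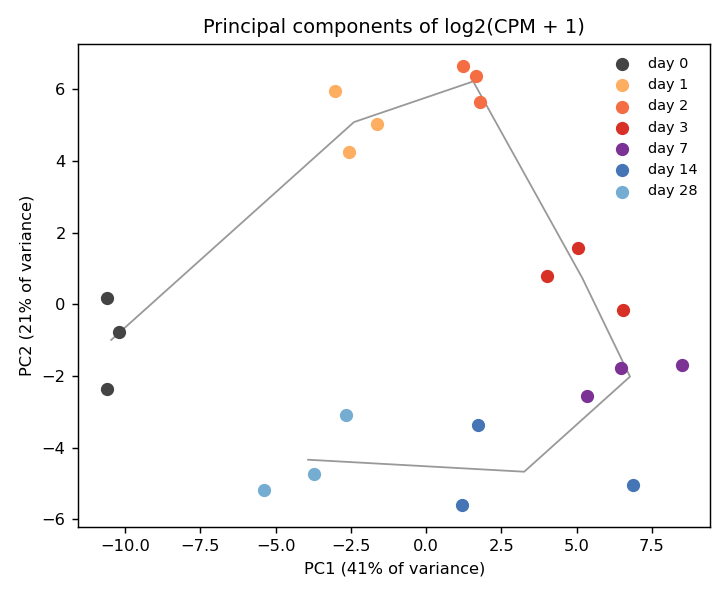
First and second principal components of log2(CPM + 1), which hold 41.1% and 20.8% of the variance, with a point per library, colour for the day, and a line through the day means. Day 0 lies at a mean of -10.46 on the first component and day 7 at 6.77.

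Day 1 against day 0 asks what changed first. miR-21-5p, which is processed from a transcript overlapping Vmp1 and is known to rise in injured kidney, rose from 14740 ± 1627 to 59412 ± 3548 CPM (log2 fold change 2.02, SE 0.15, adjusted p = 4.42e-09, n = 3 per day in limma). The other arm of its precursor, miR-21-3p, rose by 2.64 on the log2 scale. miR-132-3p rose from 51.3 ± 5.25 to 243 ± 25.8 CPM (2.22) and its genomic neighbour miR-212-3p by 2.44. miR-19a-3p rose by 1.81 and miR-223-3p, a myeloid miRNA, by 1.69. The largest falls were those of miR-720 (-1.01), miR-101a-5p (-0.91, from 55.6 ± 4.18 to 29.2 ± 1.98 CPM), miR-1981-3p (-0.82), miR-193-3p (-0.74), miR-363-3p (-0.70) and miR-33-5p (-0.63). In all, 61 miRNAs were higher and 48 lower (65 and 27 with library totals).

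Of 16 miRNAs associated with injury and fibrosis, 7 rose and 1 fell by day 1, and 8 rose and 1 fell when adjusted over the list alone. That list was drawn up with this model in mind and is not independent evidence. It passed camera (adjusted p = 0.000109), with adjusted p = 0.232 with an estimated correlation. Of 8 miRNAs induced by NF-kB, 6 rose and 1 fell, in both adjustments, with miR-146b-5p at 1.17 and miR-155-5p at 0.70. The 1 that fell was miR-146a-5p (-0.59). Camera gave adjusted p = 0.000172, and adjusted p = 0.135 with an estimated correlation. The list shares miR-146b-5p, miR-21-5p, miR-132-3p and miR-212-3p with the injury and fibrosis list. Of 14 members of the miR-17 to miR-92 clusters, known from proliferating cells, 7 rose in both adjustments, among them miR-18a-5p (1.45), miR-92a-3p (1.06) and miR-17-5p (1.01), with camera adjusted p = 0.00026 and adjusted p = 0.135 with an estimated correlation. Of 7 members of the miR-30 family, 3 fell in both adjustments, among them miR-30e-5p and miR-30e-3p (both -0.62), with camera adjusted p = 0.00869 and adjusted p = 0.373 with an estimated correlation. miR-192-5p fell by 0.48 on the log2 scale, from 120890 ± 10417 to 86462 ± 6887 CPM. Of 4 erythroid miRNAs 1 was higher, and 2 when adjusted over the list alone. The 1 was miR-451, which rose from 393 ± 159 to 1161 ± 597 CPM (1.52, adjusted p = 0.0164). That call was lost without day 0 replicate 3 (adjusted p = 0.104) and without day 1 replicate 2 (adjusted p = 0.0957). The call of miR-363-3p was lost without any of the 3 day 0 libraries (adjusted p = 0.0593, 0.0609 and 0.0671), without day 1 replicates 1 and 2 (0.0607 and 0.0946) and with no filter (0.111).

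Day 2 against day 0 asks how far the early change had gone. miR-21-3p rose by 3.16, from 169 ± 39.0 to 1494 ± 157 CPM (SE 0.20, adjusted p = 1.83e-10, n = 3 per day in limma), and miR-21-5p by 2.39, to 77268 ± 8332 CPM. miR-212-3p rose by 2.64, miR-132-3p by 2.38, miR-298-5p by 2.38 and miR-18a-5p by 2.08. miR-30e-5p, which lies in an intron of Nfyc in GRCm38, fell by 1.08, from 27379 ± 3481 to 12865 ± 616 CPM. miR-20b-5p (-1.41), miR-3073b-3p (-1.12), miR-363-3p (-1.11), miR-874-3p (-1.08) and miR-1968-5p (-1.06) fell as well. In all, 105 miRNAs were higher and 82 lower. With library totals, which moved the median of all miRNAs by 0.18, 143 were higher and 47 lower.

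The miR-30 family fell as a group by day 2: all 7 tested members were lower in both adjustments, with a median of -0.60, and miR-30a-5p fell by 0.60 and miR-30c-5p by 0.70. Camera gave adjusted p = 0.000669, and adjusted p = 0.246 with an estimated correlation. miR-30a-3p (-0.29) lost its call without day 0 replicates 1 and 2 and day 2 replicate 3 (adjusted p from 0.0593 to 0.145), and with library totals neither it (0.578) nor miR-30b-5p (0.0944) passed. Of 9 kidney-enriched miRNAs, 5 fell in both adjustments, among them miR-192-5p (-0.78), miR-215-5p (-0.80) and miR-190-5p (-0.91), with camera adjusted p = 0.0218 and adjusted p = 0.236 with an estimated correlation. The other members called, miR-10b-5p and miR-196b-5p, were lost without day 0 replicate 2 or any day 2 library (adjusted p from 0.0580 to 0.173) and without day 0 replicate 1 or day 2 replicate 3 (0.0502 and 0.0516). With library totals neither passed (0.108 and 0.374), and miR-10b-5p was also lost with no filter (0.113). Of the 16 injury and fibrosis miRNAs, 11 rose and 1 fell in both adjustments (camera adjusted p = 2.82e-05, adjusted p = 0.185 with an estimated correlation). Of 12 leukocyte miRNAs, 8 rose and 2 fell in both adjustments, with miR-223-3p at 2.06 and miR-142-3p, a miRNA of blood cells, at 1.16. Camera gave adjusted p = 0.0254, and adjusted p = 0.459 with an estimated correlation. The 2 that fell were miR-146a-5p (-0.82) and the lymphocyte miRNA miR-150-5p (-0.66, lost with library totals, adjusted p = 0.0662). The NF-kB list had 6 higher and 1 lower of 8 in both adjustments (camera adjusted p = 0.00154, adjusted p = 0.166 with an estimated correlation). The 1 lower was again miR-146a-5p. Of the 14 miR-17 to miR-92 members, 9 rose and 2 fell, and 11 rose and 2 fell when adjusted over the list alone, with camera adjusted p = 0.000704 and adjusted p = 0.135 with an estimated correlation. Erythroid miR-451 stood at 1329 ± 449 CPM (1.79, adjusted p = 0.00282), and 3 of 4 erythroid miRNAs were higher in both adjustments (camera adjusted p = 0.201). Of these, miR-486-5p (1.59) lost its call without day 0 replicate 3 (adjusted p = 0.0958), and miR-144-3p (1.27) without day 0 replicates 1 and 3 and day 2 replicates 1 and 2 (adjusted p from 0.0502 to 0.189), with no filter (0.107), with robust empirical Bayes (0.0881) and in DESeq2 (0.0560). The endothelial miR-126-3p, whose gene overlaps Egfl7 in GRCm38, fell by 0.49.

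Day 3 against day 0 asks about the end of the early phase. miR-298-5p rose by 3.24, from 2.48 ± 0.647 to 32.0 ± 6.91 CPM (SE 0.26, adjusted p = 3.70e-09, n = 3 per day in limma). miR-146b-5p, an NF-kB target, rose by 2.63, from 102 ± 22.2 to 647 ± 183 CPM. miR-214-3p, from the Dnm3os transcript in GRCm38, rose by 2.37, from 46.8 ± 3.33 to 248 ± 35.5 CPM. miR-21-3p (2.73), miR-212-3p (2.72) and miR-132-3p (2.48) stayed among the largest rises. miR-3073b-3p (-1.39), miR-20b-5p (-1.20), miR-3073b-5p (-1.18) and miR-874-3p (-1.10) fell. In all, 131 miRNAs were higher and 82 lower. With library totals, which moved the median of all miRNAs by 0.17, 145 were higher and 50 lower.

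The 6 mesenchymal miRNAs of the miR-199 and miR-214 cluster were all higher by day 3 in both adjustments, with miR-214-5p at 1.45, miR-199a-5p at 1.01 and a median of 0.84. Camera gave adjusted p = 0.00448, and adjusted p = 0.35 with an estimated correlation. All 6 are also in the injury and fibrosis list, and miR-199a-3p and miR-199b-3p among them hold identical reads. miR-199b-5p lost its call without day 0 replicate 2 (adjusted p = 0.0814) and day 3 replicate 2 (0.100). Of 16 injury and fibrosis miRNAs, 14 rose and 1 fell in both adjustments (camera adjusted p = 1.43e-06, adjusted p = 0.152 with an estimated correlation). Of 12 leukocyte miRNAs, 9 rose in both adjustments, with miR-223-3p at 2.32, miR-142-3p at 2.02 and miR-342-3p at 1.23 (camera adjusted p = 0.000629, adjusted p = 0.236 with an estimated correlation). The NF-kB list had 6 of 8 higher in both adjustments (camera adjusted p = 0.0011, adjusted p = 0.163 with an estimated correlation). Of the 14 miR-17 to miR-92 members, 12 rose and 2 fell in both adjustments (camera adjusted p = 0.00122, adjusted p = 0.135 with an estimated correlation). Those that rose included miR-18a-5p (2.27) and miR-19a-3p (1.97), and the 2 that fell were miR-20b-5p and miR-106a-5p (-0.72). All 7 miR-30 members were lower in both adjustments, with a median of -0.63 (camera adjusted p = 0.000659, adjusted p = 0.246 with an estimated correlation). miR-30d-5p (-0.37) lost its call without day 0 replicate 2 and day 3 replicates 1 and 3 (adjusted p from 0.0605 to 0.0812) and with library totals (0.0702), as did miR-30a-3p with library totals (0.114). Among kidney-enriched miRNAs 4 fell and 1 rose in both adjustments (camera adjusted p = 0.154), with miR-192-5p at -0.71 and miR-204-5p, from an intron of Trpm3, at 0.38. Of the 4, miR-10b-5p was lost without day 0 replicate 2 and day 3 replicates 1 and 3 (from 0.139 to 0.213), with library totals (0.145), with no filter (0.130) and with the replicate block (0.0520). All 5 miR-34 members, induced by p53, were higher in both adjustments, with miR-34c-3p at 1.34, and camera did not pass (adjusted p = 0.0639). The miR-183 cluster had all 4 members higher in both adjustments, with miR-183-5p at 1.71, and camera did not pass (adjusted p = 0.0548). Its miR-183-3p lost its call without day 0 replicate 1 (0.136). The erythroid miR-144-5p (-1.55, adjusted p = 0.0221) and miR-144-3p (-1.33, adjusted p = 0.029) were called lower, and both calls were lost without day 0 replicate 1, day 0 replicate 2 or day 3 replicate 2 (adjusted p from 0.0568 to 0.094). Both were lost too with no filter (0.0516 and 0.0656) and with robust empirical Bayes (0.0595 and 0.0701). That of miR-144-3p was also lost without day 3 replicate 3 (0.0750) and with library totals (0.0501).

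Day 7 against day 0 asks about the later phase, with 128 miRNAs higher and 98 lower. Its count of 226 was above that of day 3 (213) here, but with no filter day 3 had 217 and day 7 216, and in fits of the 2 days compared 206 and 203. miR-298-5p was higher by 3.11, and miR-146b-5p by 2.68, at 672 ± 210 CPM (SE 0.20, adjusted p = 2.30e-09, n = 3 per day in limma). miR-212-3p was higher by 2.64, miR-132-3p by 2.59, miR-223-3p by 2.45 and miR-21-5p by 2.37. The largest falls were those of miR-3073b-3p (-2.06), miR-3073b-5p (-1.84), miR-20b-5p (-1.44), miR-720 (-1.43), miR-363-3p (-1.33) and miR-193-3p (-1.25, from 362 ± 32.1 to 154 ± 35.9 CPM).

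All 6 mesenchymal miRNAs were higher at day 7 in both adjustments, with miR-214-3p at 2.28, miR-199a-5p at 1.70 and a median of 1.57 (camera adjusted p = 0.000183, adjusted p = 0.19 with an estimated correlation). Of 12 leukocyte miRNAs 9 rose, and 11 rose when adjusted over the list alone, with miR-142-3p at 2.08, miR-342-3p at 1.71 and the macrophage miRNA miR-511-3p, scarce at day 0, at 2.50 (camera adjusted p = 0.000482, adjusted p = 0.236 with an estimated correlation). Both arms of the endothelial miR-126 were lower, miR-126-3p by -0.41 and miR-126-5p by -0.38. All 7 miR-30 members were lower in both adjustments, with a median of -0.62 (camera adjusted p = 0.00149, adjusted p = 0.3 with an estimated correlation). miR-30d-5p (-0.34) lost its call without day 0 replicate 2 and day 7 replicates 2 and 3 (adjusted p from 0.0608 to 0.0943). Among 9 kidney-enriched miRNAs 3 fell and 1 rose in both adjustments (camera adjusted p = 0.291), with miR-190-5p at -1.13, miR-215-5p at -0.96, miR-192-5p at -0.87 and miR-204-5p at 0.61. The miR-29 family, known to repress collagen transcripts, had 3 of 5 lower in both adjustments, with miR-29c-3p at -0.92 and miR-29a-3p at -0.52, and camera did not pass (adjusted p = 0.0639). The other, miR-29c-5p, was lost without day 0 replicate 3 and day 7 replicates 1 and 3 (adjusted p from 0.0584 to 0.192), with library totals (0.103) and with no filter (0.0514). Of 7 miR-200 family members, known from epithelium, 3 fell and 1 rose in both adjustments, with miR-200a-3p at -0.51 and miR-200c-3p at 0.61 (camera adjusted p = 0.487). The injury and fibrosis list had 14 higher and 1 lower of 16 in both adjustments (camera adjusted p = 1.58e-07, adjusted p = 0.135 with an estimated correlation). The miR-17 to miR-92 list had 12 higher and 2 lower of 14 in both adjustments (camera adjusted p = 0.00149, adjusted p = 0.135 with an estimated correlation). The NF-kB list had 5 of 8 higher, and 6 when adjusted over the list alone (camera adjusted p = 0.00245, adjusted p = 0.185 with an estimated correlation). All 4 members of the miR-183 cluster were higher in both adjustments, with miR-183-5p at 1.98 (camera adjusted p = 0.0303, adjusted p = 0.373 with an estimated correlation), though miR-183-3p was lost without day 0 replicate 1 (0.0544). Of the let-7 family, 2 of 9 rose and 1 fell in both adjustments, with let-7i-5p at 1.73 and let-7e-5p at 0.69 (camera adjusted p = 0.579). The median of all let-7 members (0.04) and that of the miR-200 family (0.03) turned negative with RLE and with upper-quartile scaling. With upper-quartile scaling 45.1% of the calls at day 7 were rises, against 56.6%, and the median of all miRNAs moved by -0.18.

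**Figure D3:**
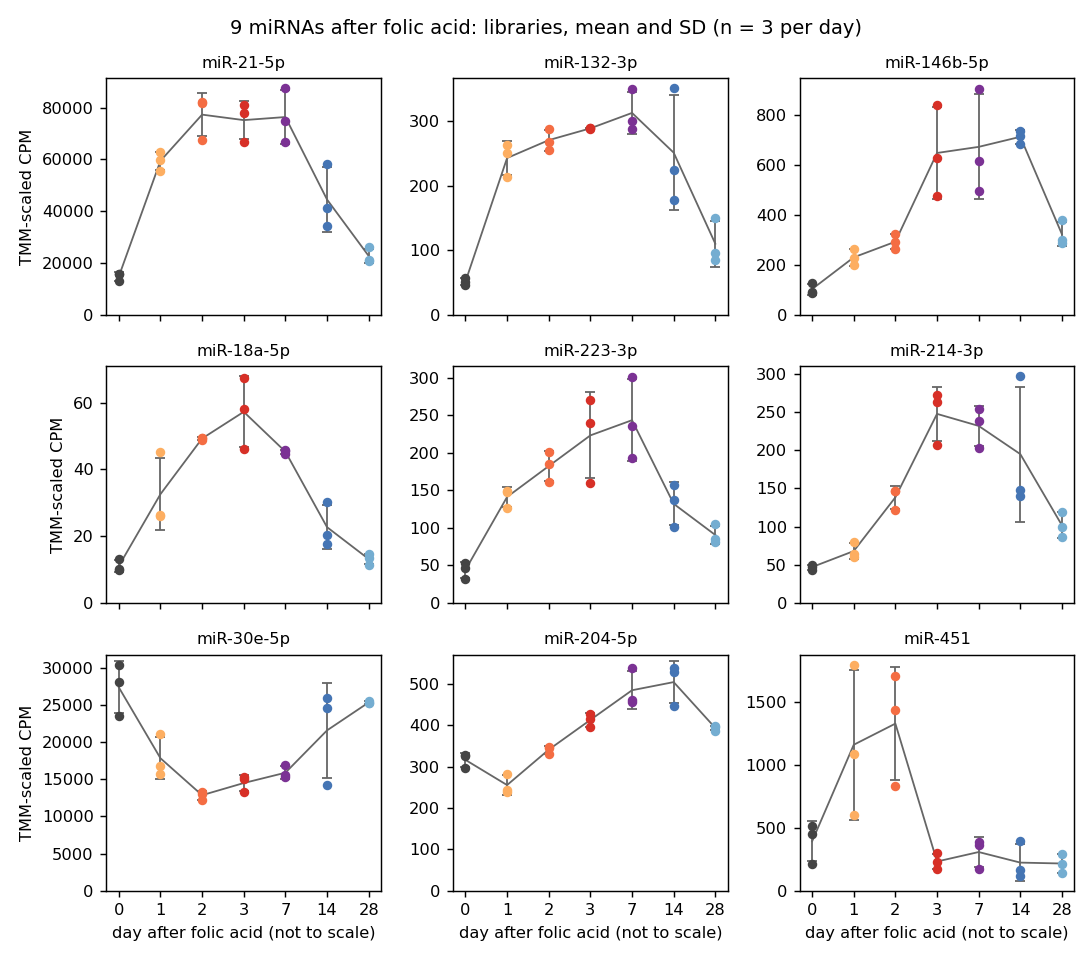
TMM-scaled CPM of 9 miRNAs against day, with a point per library and the mean ± SD of 3 libraries. Days are not to scale. miR-21-5p stood at 14740 CPM at day 0 and 76341 CPM at day 7, and miR-30e-5p at 27379 CPM at day 0 and 12865 CPM at day 2.

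Day 14 against day 0 asks what remained when the early rises had passed their peak. miR-146b-5p was higher by 2.80, at 712 ± 27.1 CPM (SE 0.20, adjusted p = 3.93e-09, n = 3 per day in limma). miR-298-5p (2.34), miR-132-3p (2.22), miR-214-3p (1.95), miR-142-3p (1.85, at 196 ± 6.66 CPM) and miR-212-3p (1.79) followed. The largest falls were those of miR-3073b-3p (-2.03), miR-720 (-1.31), miR-3968 (-1.25), miR-363-3p (-1.21), miR-193-3p (-1.19) and miR-3073b-5p (-1.12). In all, 108 miRNAs were higher and 77 lower.

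The 6 mesenchymal miRNAs stayed higher at day 14 in both adjustments, with miR-199a-5p at 1.75 and a median of 1.68 (camera adjusted p = 1.26e-05, adjusted p = 0.152 with an estimated correlation). Of 12 leukocyte miRNAs 9 were higher, and 10 when adjusted over the list alone, with miR-142-5p at 1.46, miR-342-3p at 1.49 and miR-146a-5p at 1.04 (camera adjusted p = 6.40e-05, adjusted p = 0.166 with an estimated correlation). The injury and fibrosis list had 14 higher and 1 lower of 16 in both adjustments (camera adjusted p = 8.61e-08, adjusted p = 0.135 with an estimated correlation). The NF-kB list had 6 of 8 higher, and 7 when adjusted over the list alone (camera adjusted p = 0.000729, adjusted p = 0.159 with an estimated correlation). Of the 14 miR-17 to miR-92 members 6 were higher and 1 lower, and 9 and 1 when adjusted over the list alone, and camera did not pass (adjusted p = 0.0639). Of these, miR-93-5p, miR-25-3p and miR-20b-5p were each lost without day 0 replicate 3 and day 14 replicate 3, and miR-93-5p without replicate 1 of either day (from 0.0786 to 0.251). miR-93-5p was also lost with RLE (0.0644) and upper-quartile scaling (0.0713), and with no filter or a filter of 10 CPM (0.0998 and 0.0919), and miR-20b-5p with no filter (0.0551). Of the 7 miR-30 members 3 were lower, and 4 when adjusted over the list alone (camera adjusted p = 0.0464, adjusted p = 0.498 with an estimated correlation). Camera did not pass for it with identical rows left out (0.0521). Kidney-enriched miRNAs split in both adjustments, with 3 higher and 3 lower of 9 (camera adjusted p = 0.734), miR-204-5p at 0.67 and miR-192-5p at -0.85. Of the 3 higher, miR-10a-5p and miR-196b-5p were each lost without day 0 replicate 3 and day 14 replicates 1 and 2, and miR-10a-5p without day 0 replicate 1 (adjusted p from 0.0577 to 0.216). Both were also lost with upper-quartile scaling (0.0519 and 0.0810) and with no filter (0.157 and 0.0601), miR-10a-5p in DESeq2 (0.0582) and miR-196b-5p with a filter of 10 CPM (0.0748). Outside the list, and picked after its values were seen, miR-194-2-5p was lower by 0.70 on days 7 and 14. Library day 14 replicate 3 stood apart on the first principal component, at 6.87 against 1.71 and 1.20 for the others of its day. Without it 159 miRNAs were called, against 185, and miR-3073b-3p stood at -1.39. In a fit of days 0 and 14 alone 17 of the 70 calls of named miRNAs and list members were lost, among them the 3 of the miR-30 family (miR-30a-5p, miR-30b-5p and miR-30e-3p, adjusted p = 0.0543, 0.0707 and 0.104).

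Day 28 against day 0 asks what was left at the end of the course. miR-146b-5p was still higher by 1.65, at 322 ± 48.3 CPM (SE 0.20, adjusted p = 8.17e-06, n = 3 per day in limma). miR-31-5p (1.43, from 48.9 ± 10.9 to 131 ± 10.7 CPM), miR-298-5p (1.42), miR-214-5p (1.21), miR-142-5p (1.20) and miR-199a-5p (1.20) were also higher. Lower were miR-720 (-0.80), miR-33-5p (-0.74), miR-193-3p (-0.73), miR-101a-5p (-0.66), miR-101c (-0.55) and miR-378-5p (-0.37). In all, 48 miRNAs were higher and 8 lower. The number of falls depended on the scaling, with 40 higher and 29 lower with upper-quartile scaling, 34 and 11 with library totals, and 38 and 15 in DESeq2.

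All 6 mesenchymal miRNAs were higher at day 28 in both adjustments, with a median of 1.18 (camera adjusted p = 8.61e-08, adjusted p = 0.135 with an estimated correlation). Of 12 leukocyte miRNAs 7 were higher, and 8 when adjusted over the list alone, with miR-142-3p at 1.12 and miR-342-3p at 1.00 (camera adjusted p = 2.81e-05, adjusted p = 0.163 with an estimated correlation). Of the 7, the scarce miR-223-5p and miR-511-3p were each lost without any 1 of the 3 day 0 libraries and without day 28 replicates 1 and 3 (adjusted p from 0.0585 to 0.142), and miR-146a-5p without day 28 replicate 1 (0.0506). miR-223-5p and miR-511-3p were also lost with library totals (0.0545 and 0.0759), with no filter (0.101 and 0.111), in edgeR (0.0638 and 0.0768) and with a pseudocount of 5 CPM (0.152 and 0.111), and miR-223-5p in DESeq2 (0.0575). The injury and fibrosis list had 11 of 16 higher, and 12 higher and 1 lower when adjusted over the list alone (camera adjusted p = 8.61e-08, adjusted p = 0.135 with an estimated correlation). The NF-kB list had 5 of 8 higher, and 6 when adjusted over the list alone (camera adjusted p = 0.00024, adjusted p = 0.135 with an estimated correlation). miR-21-5p, at 22696 ± 2866 CPM, passed (0.62), and this call was lost without day 0 replicate 3 (adjusted p = 0.079) and without day 28 replicate 3 (0.0639) and with no filter (0.0501). For the miR-30 family limma, edgeR and DESeq2 called 0 of 7, with 0 at an unadjusted p under 0.05 in limma. For the miR-17 to miR-92 list they called 0 of 14, with 1 at an unadjusted p under 0.05 in limma. Without day 28 replicate 1, 37 miRNAs were called in place of 56, and miR-193-3p (adjusted p = 0.0609), miR-720 (0.229) and miR-378-5p (0.109) no longer passed. The last of these was also lost without day 0 replicates 1 and 2 and day 28 replicates 2 and 3 (adjusted p from 0.117 to 0.144), and miR-720 without day 0 replicates 1 and 3 and day 28 replicate 3 (from 0.0913 to 0.177). With library totals and with identical rows left out neither passed (0.0525 and 0.0540 for miR-720, 0.0545 and 0.0515 for miR-378-5p). miR-720 was lost with the replicate block (0.0587), with no filter (0.0896) and with a pseudocount of 0.25 CPM (0.0541) as well.

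**Figure D4:**
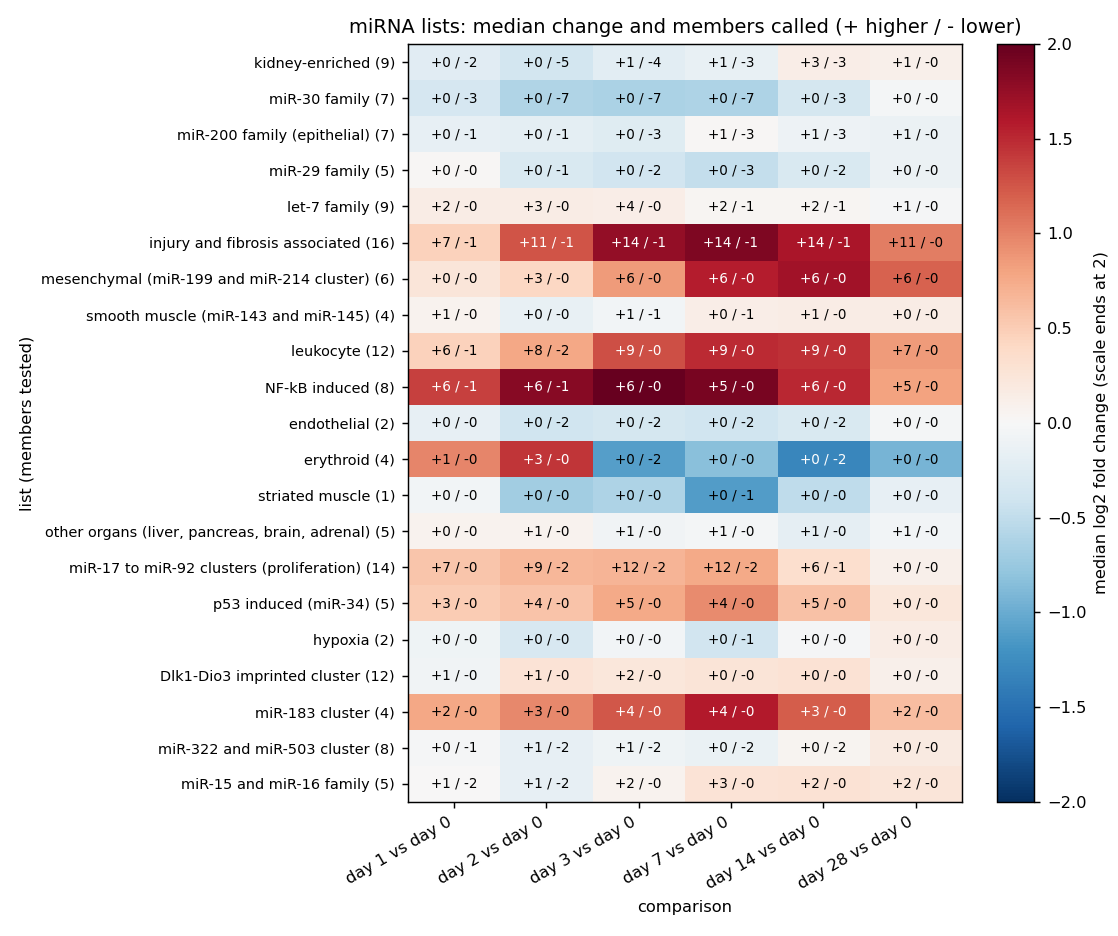
Median log2 fold change against day 0 of each list (colour), with the numbers of members called higher and lower printed in each cell, for 21 lists and 6 days. The mesenchymal list reached 6 of 6 members higher from day 3 on, 2 of them with identical reads. The miR-30 family reached 7 of 7 lower on days 2, 3 and 7. Medians near 0 can change sign with the scaling, as for the let-7 and miR-200 families at day 7.

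The mean of the late days (7, 14 and 28) was set against that of the early days (1, 2 and 3), with 9 libraries on each side. The days of a side are not replicates of a phase. SE and p-values of this comparison measure the spread between libraries within days, and levels also differed between the days of a side. miR-199a-3p, which cannot be told from miR-199b-3p, rose from 2299 ± 512 early to 5137 ± 1128 CPM late (1.16, SE 0.085, adjusted p = 8.01e-10 in limma). miR-146a-5p (1.23), miR-181c-5p (1.02), miR-181c-3p (1.01) and miR-199a-5p (0.98) were higher late. miR-21-3p fell from 1220 ± 246 to 461 ± 278 CPM (-1.63). The erythroid miR-451 (-1.56, from 908 ± 634 to 250 ± 111 CPM), miR-486-5p with its near-copy miR-3107-5p (both -1.46), miR-144-3p (-1.44) and miR-144-5p (-1.12) were lower late. In all, 85 miRNAs were higher and 76 lower.

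Of the 6 mesenchymal miRNAs 5 were higher late, and 6 when adjusted over the list alone, with a median of 0.97 (camera adjusted p = 1.27e-05, adjusted p = 0.152 with an estimated correlation). All 4 erythroid miRNAs were lower in both adjustments, with a median of -1.45 (camera adjusted p = 0.00787, adjusted p = 0.373 with an estimated correlation). Of the 14 miR-17 to miR-92 members 7 were lower and 1 higher in both adjustments, with miR-18a-5p at -0.88 and miR-92a-3p at -0.72 (camera adjusted p = 0.0136, adjusted p = 0.166 with an estimated correlation). Of the 7 miR-30 members 4 were higher in both adjustments, with miR-30e-5p at 0.45 (camera adjusted p = 0.0464, adjusted p = 0.498 with an estimated correlation). With library totals (0.0680) and, just above 0.05, with the replicate block camera did not pass for the miR-30 family. At day 7 both of these lists still stood near their day 3 medians against day 0. These were 0.76 and 0.68 for the miR-17 to miR-92 list, and -0.62 and -0.63 for the miR-30 family. Their late differences therefore do not date from day 7. Kidney-enriched miRNAs had 5 of 9 higher in both adjustments, with miR-204-5p at 0.47 (camera adjusted p = 0.0716). Of 12 leukocyte miRNAs 7 were higher and 3 lower in both adjustments, with miR-342-3p at 0.69 and miR-155-5p at -0.50 (camera adjusted p = 0.0981). With library totals 29.3% of the calls were rises, against 52.8%, and the median of all miRNAs moved by -0.11.

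Neighbouring days show when levels moved. From day 1 to day 2, 10 miRNAs rose and 2 fell, and miR-298-5p rose by 1.75, miR-214-3p by 1.02, miR-375-3p by 0.89 and miR-204-5p by 0.42. From day 2 to day 3, 16 rose and 7 fell (6 and 7 with upper-quartile scaling). All 4 erythroid miRNAs fell, miR-144-3p by 2.61, miR-451 by 2.48 (from 1329 ± 449 to 233 ± 62.7 CPM), miR-486-5p by 2.45 and miR-144-5p by 2.26. Over the same step miR-146b-5p rose by 1.11, miR-146a-5p by 0.91, miR-142-3p by 0.86 and miR-214-3p by 0.83. From day 3 to day 7, 7 rose and 1 fell (7 and 5 with upper-quartile scaling), among them miR-199a-3p (0.81), miR-199a-5p (0.69), miR-181c-5p (0.75) and miR-155-5p (-0.49). From day 7 to day 14, 5 rose and 14 fell. miR-21-3p fell by 1.14, miR-18a-5p by 1.00, miR-223-3p by 0.88 and miR-21-5p by 0.81, and miR-30e-3p rose by 0.52. In a limma fit of days 7 and 14 alone 0 miRNAs passed, with 44 at an unadjusted p under 0.05, while edgeR and DESeq2 over all days called 20 and 25. From day 14 to day 28, 20 rose and 33 fell, against 5 and 51 with library totals and 3 and 48 with upper-quartile scaling. miR-132-3p fell by 1.17, miR-146b-5p by 1.15, miR-21-5p by 0.94 and miR-214-3p by 0.86, and miR-192-5p rose by 0.49 and miR-30a-5p by 0.39. The miRNAs named for these steps were chosen after their values were seen. Counts for these steps moved by over 1.5 times with single libraries left out, and the share of rises from day 7 to day 14 was 70% with upper-quartile scaling against 26.3%.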

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

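The tests of the tubule share, of blood left in the vessels, of blood content, of a factor common to all miRNAs of a library and of reads shared between paralogs were chosen only after the results they measure were seen. The tests of scaling by library totals and of low reads were chosen before. The upper-quartile check of the leukocyte miRNAs at day 7 was not part of the rule written then. For the erythroid miRNAs the library totals do not count against scaling, so that verdict rests on the test of a common factor.

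A test of the difference between the late days (7, 14 and 28) and the early days (1, 2 and 3) called 161 miRNAs, with 9 libraries on each side. Its p-values measure the spread within days, and the days of a side are not replicates of a phase. The 12 given here are its 6 largest rises and 6 largest falls among those with a mean of at least 10 CPM. Higher late were miR-146a-5p (log2 difference 1.23), miR-199a-3p and miR-199b-3p (both 1.16, with identical reads), miR-181c-5p (1.02), miR-181c-3p (1.01) and miR-199a-5p (0.98). Lower late were miR-21-3p (-1.63), miR-451 (-1.56), miR-486-5p (-1.46), miR-3107-5p (-1.46), miR-144-3p (-1.44) and miR-144-5p (-1.12). Camera on the same difference passed for the mesenchymal list (median 0.97), the erythroid list (-1.45), the miR-30 family (0.19) and the miR-17 to miR-92 clusters (-0.17). With an estimated correlation none of these 4 lists passed, with adjusted p = 0.152, 0.373, 0.498 and 0.166. The camera call of the miR-30 family was also lost with library totals (0.0680) and, just above 0.05, with the replicate block. Of 100 regroupings of the 18 libraries, 1 called as many miRNAs as the real grouping, which is the real grouping itself (161). The highest of the others called 62. Regrouping single libraries also broke up the days, which adds the differences between days to the spread. It therefore cannot separate a difference between phases from differences between single days, and no conclusion about phase is drawn from it.

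The erythroid miRNAs were all lower late than early. Against day 0, 1 of 4 was called higher on day 1 and 3 of 4 on day 2, 2 of 4 were called lower on days 3 and 14, and 0 of 4 on days 7 and 28. No camera test of the list against day 0 passed (adjusted p = 0.225 on day 1 and 0.201 on day 2). Among them miR-486-5p was the most abundant, at 2169 ± 989 CPM on day 0, 6232 ± 2132 on day 2 and 1106 ± 286 on day 3. Scaling of the libraries is argued against. A scaling is a factor common to all miRNAs of a library and moves them alike, but the 4 erythroid miRNAs lay from -1.56 to -1.11 from the median of all miRNAs, with a median of -1.45 (median SE of a member 0.28). With library totals the late against early median was -1.58, but that scaling lowers all miRNAs in this comparison (by -0.11 at the median), so this value alone does not count against scaling. Blood content that differs from kidney to kidney stays open. Within days, the deviations of the 4 miRNAs went together over the 21 libraries (mean pairwise r = 0.919, lowest 0.870). In 1000 random lists of 4 miRNAs the highest mean r was 0.723. miR-144 and miR-451 lie next to each other in GRCm38, and miR-486-5p, from another place, held r of at least 0.901 with each. These values show that the 4 moved together within days, and they do not tell why the days differed. Blood held in each kidney stays open as a cause of the differences between days. Such blood could follow from the injury, through congestion or bleeding, or from how tissue was taken on each day, and the design does not separate these. No other biological explanation was tested.

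Called higher on days 3, 7 and 14 were 9 of 12 leukocyte miRNAs, and 6, 8 and 7 on days 1, 2 and 28, with 1 lower on day 1 and 2 lower on day 2. The median was 1.49 at day 7. With an estimated correlation camera did not pass (adjusted p = 0.236 on days 3 and 7 and 0.166 on day 14). The most abundant of them, miR-142-5p, went from 601 ± 80.0 CPM at day 0 to 1783 ± 389 at day 7. Of the 12, 2 (miR-147-3p and miR-511-5p) were at or under the floor of 3 reads at day 0, and 3 (miR-146a-5p, miR-147-3p and miR-155-5p) are also in the NF-kB list. A lower share of tubule RNA would raise the markers of other cell types alike. At day 7 the mesenchymal list did rise, with 6 of 6 higher and a median of 1.57. The smooth muscle list had 0 of 4 higher (median 0.13), and the endothelial miR-126 arms were both called lower, with a median of -0.39. These markers did not rise alike, which argues against a lower tubule share as the whole cause. The miR-126 arms come from 1 precursor, and a lower tubule share stays open as part of the cause. Scaling of the libraries is argued against. With library totals 9 of the 9 leukocyte miRNAs called at day 7 stayed called, though that scaling raised the median of all miRNAs. With upper-quartile scaling, which moved the median of all miRNAs by -0.18, 9 of the 9 stayed called as well. A factor common to all miRNAs of a library would move them alike, but the leukocyte median lay 1.42 above that of all miRNAs (median SE of a member 0.21, members from -0.27 to 2.42). Blood left in the vessels was first tested by the erythroid median at day 14 against day 0 (-1.31), where 2 of 4 were lower. Those calls were lost under several alternatives, so a further test was chosen after that value was seen. From day 2 to day 3 all 4 erythroid miRNAs fell, with a median of -2.47, while the leukocyte median was 0.53 with 4 of 12 higher. This argues against more whole blood for the step from day 2 to day 3. Against day 0, all 4 erythroid miRNAs were below 0, from -1.55 to -0.69 on day 3 and from -1.04 to -0.34 on day 7. The leukocyte medians on these days were 1.30 and 1.49. These values argue against more whole blood than at day 0 as the cause on days 3 and 7. Of the 4, only 2 were called lower on day 3 and 0 on day 7. On days 1 and 2 the leukocyte medians (0.46 and 0.77) and the erythroid medians (0.97 and 1.43) were both above day 0, so more blood stays open for that part of the rise. For the rest, blood richer in leukocytes, leukocytes within the tissue, induction in resident cells and, in part, a lower tubule share stay open as hypotheses. The samples named by the labels, whole kidneys without sorting, do not separate them.

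miR-20b-5p and miR-106a-5p were lower at day 7 while their near-copies miR-20a-5p and miR-17-5p were higher. miR-20b and miR-106a lie next to each other in GRCm38, with miR-363, whose miR-363-3p was lower too (-1.33 at day 7), and miR-20a and miR-17 lie in Mir17hg. The log2 ratio of miR-20b-5p to miR-20a-5p changed by -2.19 at day 7 (SE 0.31, adjusted p = 0.000156), and that of miR-106a-5p to miR-17-5p by -2.09 (SE 0.25, adjusted p = 6.68e-05). Reads shared between near-copies would move the members of a pair the same way, so sharing is argued against as the whole cause, though the aligner is not given. Too few reads is argued against, since the fewest reads of miR-106a-5p or miR-20b-5p in a day 7 library were 13. A lower level of the miR-106a cluster beside a higher level of the miR-17 cluster is a hypothesis left open. No biological explanation was tested, and a change of cell mix could give the same picture.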

How the results depend on the processing

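Chosen only after the data were seen were the edgeR test, the pseudocounts of 0.25 and 5 CPM, leaving out rows with identical reads, the prior count of 2, and, for single miRNAs, the fit of only the 2 days compared. Of 278 counts under alternatives, 241 lay within 1.5 times the reported count and 37 did not. With each library left out in turn, 250 to 282 miRNAs changed over time (272 reported), 82 to 99 on day 1, 151 to 176 on day 2, 188 to 205 on day 3, 193 to 214 on day 7, 159 to 188 on day 14 and 143 to 161 in late against early. Other settings gave 232 to 281 over time, and 88 to 111, 169 to 193, 181 to 217, 188 to 227, 134 to 189 and 41 to 69 on days 1, 2, 3, 7, 14 and 28, and 139 to 167 in late against early. Where a leave-out leaves 2 libraries, the spread is pooled over all days.

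Counts that moved by more were mostly those between neighbouring days. Leaving out a library gave 37 (without day 28 replicate 1) to 57 on day 28, 2 (without day 2 replicate 1) to 12 for day 2 against day 1, and 6 (without day 3 replicate 2) to 17 for day 3 against day 2. It gave 4 to 21 (without day 7 replicate 3) for day 7 against day 3, 5 (without day 14 replicate 2) to 46 (without day 14 replicate 3) for day 14 against day 7, and 11 (without day 28 replicate 2) to 70 (without day 14 replicate 1) for day 28 against day 14. With no filter, where more miRNAs are tested, the 5 steps gave 6, 9, 3, 8 and 19, against 12, 23, 8, 19 and 53. DESeq2 gave 22 for day 2 against day 1 and 21 for day 7 against day 3, and upper-quartile scaling 13 for day 3 against day 2. A fit of only the 2 days compared, with fewer libraries, gave 20 for day 2 against day 1, 24 for day 28 against day 14 and 0 for day 14 against day 7 in limma, where 44 had an unadjusted p under 0.05 and edgeR and DESeq2 in the full fit called 20 and 25. For the list tests, 0 passed with an estimated correlation (26 unadjusted) and 73 with fry, against 36. For the other moved counts the cause was not tested. A block on replicate number gave 265 over time and 154 in late against early, and the numbers do not pair libraries (mean r = 0.016, 0.0016 and -0.0047 for replicates 1, 2 and 3).

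Scaling moved the split between rises and falls. With library totals the share of rises was 70.7% on day 1 (56.0% reported), 75.3% on day 2 (56.2%, median of all miRNAs moved by 0.18), 74.4% on day 3 (61.5%, 0.17), 75.6% on day 28 (85.7%), 100% for day 2 against day 1 (83.3%, 0.10) and 8.93% for day 28 against day 14 (37.7%, -0.12). With upper-quartile scaling it was 58.0% on day 28 (-0.12), 38.2% in late against early (52.8%), 46.2% for day 3 against day 2 (69.6%), 5.88% for day 28 against day 14 and, with a shift of 0.14, 70% for day 14 against day 7. For day 7 against day 3 the share was 58.3% with upper-quartile scaling and 66.7% with library totals (87.5% reported). DESeq2 gave 71.7% on day 28.

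Of 452 named results, 340 kept their call under each alternative that gave them a value and 112 lost it under at least 1. The filter of 10 CPM gave no value for 23, leaving out identical rows for 5, and the fit of only the 2 days for 68, among them those of late against early. That fit lost 29 of 384 calls, 17 of them on day 14. In 9272 comparisons 577 lost the call and 0 changed direction. Depth limits the scarce miRNAs, since 3 reads are 1.04 CPM in the shallowest library.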

Other observations

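The test of arm ratios was chosen only after unequal arms had been seen. The regroupings were chosen before.

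The miR-375-3p of the other-organ list rose from a mean of 189 CPM at day 0 to 667 ± 67.3 at day 7 (1.81) and was still higher at day 28 (0.67), the only 1 of the 5 members tested to be called in a comparison with day 0. The list's camera tests did not pass (adjusted p = 0.750 at day 7), and its median at day 7 (-0.04) was positive with library totals. The miR-322 and miR-503 cluster did not move as 1 group. On days 2 and 3, 1 of 8 was higher, miR-351-5p, and members other than it, miR-322-3p and miR-450a-5p were not called on any day. miR-322-3p fell on days 1 to 14 (-0.76 at day 3), and miR-450a-5p on days 2, 3, 7 and 14 (-0.56 at day 7). Its call at day 14 (-0.44, adjusted p = 0.0433) was lost with library totals (0.0878), no filter (0.0889), the replicate block (0.0518), identical rows left out (0.0561) and a fit of the 2 days alone (0.122), and without replicate 3 of day 0 (0.1995) or of day 14 (0.155). At day 7, 2 of 8 were lower (camera adjusted p = 0.322). Of the miR-15 and miR-16 family, miR-15b-5p rose to 158 ± 15.8 CPM at day 3 from 61.0 ± 3.82 (1.36). On days 1 and 2, miR-15a-5p and miR-497-5p were lower and 1 of the 5 was higher, in both adjustments. At day 7, 3 of 5 were higher (camera adjusted p = 0.187). Of the 3, miR-195-5p (0.28) was lost under RLE (0.0894), upper-quartile (0.514) and several other alternatives. Smooth muscle miRNAs had 0 of 4 higher and 1 lower at day 7, miR-145-3p (camera adjusted p = 0.933). That call was not made when adjusted over the list alone. It was lost with library totals (0.130) and in a fit of the 2 days alone (0.0510). It was also lost without day 0 replicate 3, day 7 replicate 1 or day 7 replicate 2 (from 0.0679 to 0.122). On days 1, 3 and 14, 1 of the 4 was called higher, miR-145-5p, and on day 3 miR-145-3p was lower.

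Of 12 members of the imprinted Dlk1-Dio3 cluster, limma, edgeR and DESeq2 called 0 at day 7, with 0 at an unadjusted p under 0.05 in limma (camera adjusted p = 0.850). At day 3, 2 of 12 were higher, the scarce miR-409-3p (1.34) and miR-541-5p (0.85), and the latter was lost without day 0 replicate 3 (0.143) and day 3 replicate 2 (0.0709). The hypoxia miRNA miR-210-3p stood at 0.06 at day 7 and miR-210-5p at -0.82, a call lost without day 0 replicate 1 (0.0634), day 0 replicate 2 (0.140) and day 7 replicate 2 (0.0617). The striated muscle miR-133a-3p fell at day 7 from 29.4 ± 7.88 to 13.2 ± 4.71 CPM (-1.11).

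Higher than day 0 on all 6 later days were 19 miRNAs and lower 6, where independent lists of the same sizes would share 0.037 and 0.0013. In 20 simulations without effect the highest number was 0 in both directions, which says little, since without effect a single comparison called 0 of 431 as well. The simulations leave out the effects and the independent lists leave out the shared day 0 libraries, so part of the excess over either can come from sharing these. Of all miRNAs, 8 were called higher on some day and lower on another.

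A hypothesis is that the arms of some precursors changed unequally. A change of the precursor's transcription alone would not give that once levels have settled, though it may do so while they move. The ratios of 150 arm pairs were tested in 6 comparisons with day 0 and adjusted together with the 2 ratios of near-copies given above, which are not counted here. Of the arm ratios, 93 tests passed (228 at an unadjusted p under 0.05), from 47 of the 150 pairs and from 30 of the 88 pairs with both arms at 10 CPM or more. Examples, as 3p less 5p and chosen after their values were seen, are miR-27a at day 2 (-1.47), miR-181c at day 3 (1.10), miR-28 at day 1 (1.08), miR-214 at day 3 (0.92) and miR-21 at day 2 (0.77). Unequal stability of the arms may play a part, as may reads of an arm from another locus, and neither was tested. For scarce arms the added constant of 1 CPM shrinks the change of that arm and so moves the ratio.

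The libraries were regrouped at random. Over the whole course, 1 of 100 groupings, the real one, called as many as the real 272, and the highest of the others called 15. A random split of these libraries into days is excluded at that resolution. Libraries were moved singly, and the labels do not state that those of a day came from separate animals. The regrouping therefore cannot exclude differences between animals or preparations that the libraries of a day may share. For 3 libraries against 3, only 10 splits exist, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, reached the real count. The highest of the other splits called 0 on days 1, 2, 3 and 7 (real counts 109, 187, 213 and 226), 2 on day 14 (185) and 1 on day 28 (56). Between neighbouring days it called 0 for day 2 against day 1 (12), 0 for day 3 against day 2 (23), 1 for day 7 against day 3 (8), 15 for day 14 against day 7 (19) and 0 for day 28 against day 14 (53).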
